A study of Homo sapiens with 6 samples.

How the data were processed

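RNA sequencing libraries of MOLM13 cells were compared between 3 groups of 2 libraries each, a non-targeting hairpin (shNS) and the NAT10 hairpins shNAT10-1 and shNAT10-2, which the labels describe as established knockdown lines. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, cutadapt 4.1, HISAT2 2.1.1, HTSeq 2.0.2 and DESeq2 (version not given) were used with the build hg38; the role of each tool, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of its antisense partner cannot be told apart. The authors deposited a table of raw read counts per gene and library, with 60286 genes and no normalization. The authors also deposited, for each hairpin against shNS, a log2 fold change per gene. An adjusted p-value per gene was deposited in the same tables, with 24582 and 24245 genes listed; their column of mean levels was not used here. These tables were set beside the tests made here. A DESeq2 fit over the 4 libraries of the groups compared, added after the data were seen, gave log2 fold changes within 0.01 of all 24571 and 24236 deposited values it could be matched to, and 4057 and 3063 calls.

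The counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM factors and with filterByExpr at its minimum count of 10 and minimum total of 15. All 6 libraries entered 1 fit without covariates, so that the 3 groups shared 1 estimate of the spread, because 2 libraries per group leave few degrees of freedom. Contrasts were each hairpin against shNS, and shNAT10-2 minus shNAT10-1. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05, and log2 fold changes used edgeR's prior count of 0.125. CPM were scaled with the TMM factors. The common biological coefficient of variation was 11.4%, and the median prior degrees of freedom were 45.1. Totals ran from 7800350 to 9881073 counts per library. The 10 most abundant genes took 7.59% ± 0.32 (SD, n = 2) of counts in shNS, 10.2% ± 0.23 (SD, n = 2) with shNAT10-1 and 10.9% ± 0.45 (SD, n = 2) with shNAT10-2, and protein-coding genes took 94.5%, 94.4% and 94.4%.

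The contrasts, tests, naming rule and 32 gene lists were chosen before the data were examined, the lists from textbook knowledge of leukemia cells, amino acid metabolism, ribosome production, the cell cycle and stress responses. The lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. An estimated correlation and the self-contained test fry were tried as alternatives. Some lists had larger p-values with an estimated correlation although the estimate lay under the preset 0.01. A call lost that way therefore does not by itself show that the genes of a list are correlated. Genes named in the text are NAT10; the 10 highest and 10 lowest genes called the same way by both hairpins, ranked by the smaller change; the 5 highest and 5 lowest of each contrast; up to 4 members of each list with the smallest p-values, and members needed where a list went both ways; and PHGDH, PSAT1, PSPH, SHMT2, SLC1A4, HOXA9, MEN1, MEIS1, MYC, BCL2 and CDKN1A. The ranked genes needed a mean log2 CPM of at least 3, a symbol, and both libraries of a hairpin on the same side of both shNS libraries. Other genes are said to be singled out afterwards. Some members of the lists are not reported here by name. A fold against a group with 0 counts in both libraries was computed against a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact 95% counting interval.

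Both contrasts share the shNS libraries, so overlap and correlation were set beside 20 simulated draws of unchanged groups that shared simulated controls, from seed 1. The tests were checked on simulated counts for the 15511 tested genes with 200 changed genes. Against shNS, shNAT10-1 recovered 40.3% of 1.5-fold, 59.7% of 2-fold and 77.3% of 4-fold changes, with 5 false calls among 123 (4.07%). The simulated shNAT10-2 contrast recovered 26.9%, 65.7% and 86.4%, with 6 false calls among 125 (4.80%). In a further simulation every member of 2 lists was lowered 2-fold with shNAT10-1. Both shifted lists were found and 0 of the others. Each gene was drawn on its own, so this cannot check the preset correlation for lists whose members vary together. Alternatives were RLE factors, library totals alone, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit over the groups compared alone, a minimum log2 fold change of 1, and each library left out in turn. Fits without the interferon and antigen presentation lists were added after seeing the data. Coordinates are from GENCODE release 29 on hg38, and figures were drawn with Python 3.11.15. Genes on chromosome Y were left out of the chromosome check. NAT10 protein, cytidine acetylation and the hairpin sequences were not analysed here.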

Results

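Messenger RNA was sequenced from MOLM13 cells, an established human acute myeloid leukemia line that carries an MLL fusion gene and an activating FLT3 duplication. The cells expressed a non-targeting short hairpin RNA (shNS) or 1 of 2 hairpins against NAT10 (shNAT10-1 and shNAT10-2). NAT10 encodes an enzyme that acetylates cytidines in RNA and takes part in ribosome production. Each of the 3 groups had 2 libraries, and the question was how NAT10 knockdown changes gene expression in these cells. Total counts per library were 9261542 and 9881073 for shNS, 7800350 and 9044100 for shNAT10-1, and 9284545 and 8061096 for shNAT10-2. Of 60286 genes in the count table, 15511 had enough counts to be tested, 11702 of them protein-coding. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples. Values after ± are standard errors of log2 fold changes unless given as SD. They were computed back from the fold change and the statistic of its quasi-likelihood test. Where a group had few counts and the fold was large, they can be smaller than the counting error.

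NAT10 transcripts were reduced by both hairpins. NAT10 (ENSG00000135372.10, hg38 chromosome 11, 34105602 to 34147670, plus strand) had 935 and 825 counts in the shNS libraries, 176 and 210 with shNAT10-1, and 328 and 225 with shNAT10-2. Its mean scaled level was 88.8 CPM ± 9.91 (SD, n = 2) in shNS, 24.0 ± 0.591 (SD, n = 2) with shNAT10-1 and 31.4 ± 4.69 (SD, n = 2) with shNAT10-2. The edgeR log2 fold change against shNS was -1.88 ± 0.16 with shNAT10-1 (adjusted p = 8.89e-14), which left 27.1% of the control level (95% confidence interval 21.8 to 33.7%). With shNAT10-2 it was -1.50 ± 0.16 (adjusted p = 4.78e-11), which left 35.5% (28.7 to 43.8%). The difference between the hairpins, shNAT10-2 minus shNAT10-1, was 0.39 ± 0.17 and was not called (adjusted p = 0.0623).

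**Figure D1:**
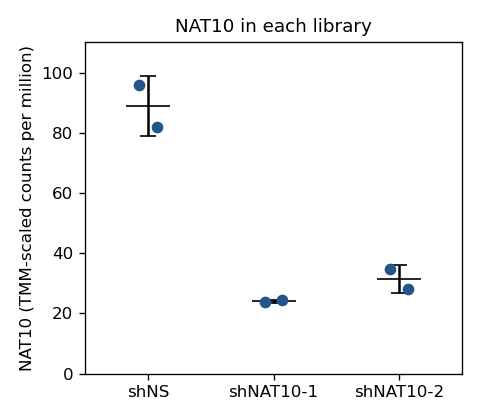
NAT10 level in each library, in TMM-scaled CPM, by group; points are the 2 libraries of a group, and the bar with whiskers is their mean and SD. Group means were 88.8, 24.0 and 31.4 CPM for shNS, shNAT10-1 and shNAT10-2.

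Cells with shNAT10-1 carried fewer transcripts of the machinery that copies and divides the genome, and more transcripts that mark maturing monocytes and macrophages. Genes for making serine, for charging transfer RNAs and for the ATF4 response, which restores amino acid supply under stress, were lower. Lysosomal, iron-handling and inflammatory genes were higher, and interferon-response genes were lower. In total 5614 genes changed against shNS (36.2% of those tested), 2813 higher and 2801 lower, and 2232 of them by at least 2-fold. Scaling by library totals alone shifted the median of all genes from 0.02 to -0.11 and gave 2147 genes higher and 3571 lower, so 37.5% of calls were higher in place of 50.1%. The 32 gene lists tested were fixed before the data were examined, and 17 of them moved as sets by camera, 9 up and 8 down. Of these, 10 also passed with an estimated correlation, each at an adjusted p of 0.0378, namely the serine, ATF4, aminoacyl-tRNA synthetase, S-phase, G2/M, monocyte, interferon, NF-kB, lysosome and iron lists. In all 30 list results that passed against shNS under either hairpin, both knockdown libraries lay on the same side of the mean of the control libraries. Where a count adjusted over the list alone is not given, it was identical to the count over all genes.

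Genes of the cell cycle were lower with shNAT10-1. All 37 tested genes of the G2/M and mitosis list fell (median log2 fold change -1.30, camera adjusted p = 4.30e-23), among them the DNA topoisomerase TOP2A, the kinase CDK1, and the proliferation marker MKI67. TOP2A (ENSG00000131747.15, chromosome 17, 40388516 to 40417950) fell by 1.94 ± 0.13 on the log2 scale, from 2139 and 2014 counts to 419 and 456 (edgeR adjusted p = 1.03e-16). CDK1 had a log2 fold change of -1.83, MKI67 of -1.46 and the spindle factor TPX2 of -1.56. Of 40 DNA replication and S-phase genes, 34 fell and none rose (35 fell adjusted over the list alone; median -1.01, camera adjusted p = 2.52e-17). The replication fork components GINS1 (-3.42), CDC45 (-2.15), MCM6 (-1.44) and MCM7 (-1.18) were among them. Ribosome biogenesis factors, which assemble ribosomes in the nucleolus, followed with 36 of 63 lower and 0 higher (38 lower adjusted over the list alone; median -0.41, adjusted p = 5.88e-07), including NHP2 (-1.53), LYAR (-1.55) and NOP58 (-1.05). That list's call was lost when camera estimated the correlation among genes (adjusted p = 0.138 with an estimated correlation). Messenger RNAs of the ribosomal proteins themselves did not move as a set (10 higher and 7 lower of 77; 8 and 6 adjusted over the list alone; median 0.07, adjusted p = 0.457). Their median was -0.06 when scaled by library totals. Leaving out shNS replicate 2 or shNAT10-1 replicate 1 gave them medians of 0.18 and 0.17 and adjusted p-values of 0.00946 and 0.0121.

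Amino acid supply genes were strongly reduced with shNAT10-1. Serine is built from a glycolytic intermediate by PHGDH, PSAT1 and PSPH, and SHMT2 passes its carbon on to folate. PHGDH (ENSG00000092621.13, chromosome 1, 119648411 to 119744226) dropped from 1712 and 2094 counts to 65 and 97 (log2 fold change -4.25 ± 0.17, edgeR adjusted p = 1.52e-25). Next came PSAT1 (-3.32 ± 0.14, adjusted p = 6.10e-25), PSPH (-1.70), SHMT2 (-1.30), the mitochondrial folate enzyme ALDH1L2 (-2.61) and the transporter SLC38A1 (-1.73). The neutral amino acid transporter SLC1A4 was not called (-0.13, adjusted p = 0.502). Of 23 serine, glycine and one-carbon genes, 14 fell and 4 rose (median -0.65, camera adjusted p = 1.65e-13). Of 28 genes of the ATF4 list, 21 fell and 2 rose (median -1.24, adjusted p = 4.30e-23), led by the pseudokinase TRIB3 (-4.67 ± 0.18), the growth inhibitor DDIT4 (-3.36), the transaminase GPT2 (-3.45) and the secreted STC2 (-5.23). Of 20 cytosolic aminoacyl-tRNA synthetases, 16 fell and 0 rose (median -0.73, adjusted p = 1.29e-10), with IARS1 at -1.57, CARS1 at -1.65 and GARS1 at -1.22.

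Myeloid maturation, lysosomal and iron-handling genes rose together with shNAT10-1. The monocyte and macrophage list had 26 of 34 genes higher and 5 lower (27 and 5 adjusted over the list alone; median 1.17, camera adjusted p = 7.66e-19). Lysozyme, LYZ (ENSG00000090382.7, chromosome 12, 69348341 to 69354234), rose by 2.33 ± 0.12 on the log2 scale, from 11058 and 12197 counts to 46177 and 47836 (edgeR adjusted p = 6.07e-21). NCF1, a subunit of the phagocyte oxidase, rose by 1.67, and the lectin LGALS3 by 1.62, but the Fc receptor chain FCER1G fell (-0.50). NCF1 has near-identical copies, so its read assignment is uncertain. Autophagy and lysosome genes showed 26 of 30 higher and 1 lower (median 0.91, adjusted p = 9.20e-17), with PSAP and CTSD each at 2.07. In the iron, ferroptosis and oxidative stress list 18 of 22 rose and 2 fell (19 and 2 adjusted over the list alone; median 0.77, adjusted p = 1.40e-13), led by NQO1 (3.20), ferritin light chain FTL (2.28), whose processed pseudogenes can share reads, and HMOX1 (2.16). Immediate early genes, the first to respond to growth signals, had 16 of 22 higher and 1 lower (median 0.95, adjusted p = 3.89e-14), including EGR2 (2.69), EGR3 (3.33) and KLF2 (2.50), while MYC was lower (-1.13). The call of the immediate early list was lost at an adjusted p = 0.123 with an estimated correlation. Granule genes of neutrophils and promyelocytes went both ways (5 higher and 6 lower of 14; median 0.03, mean 0.02, test direction down, adjusted p = 0.905), with RNASE2 at 2.23 and CTSG at -1.19. Their median was -0.10 when scaled by library totals.

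Immune genes split with shNAT10-1. The NF-kB and inflammatory cytokine list had 20 of 23 higher and 1 lower (median 1.14, camera adjusted p = 4.82e-11), with EBI3 at 2.15, CXCL8 at 1.78 and SOD2 at 1.47; the single lower gene was the interferon-induced CXCL10 (-4.59). Interferon-response genes fell in 30 of 39 cases and rose in none (32 lower adjusted over the list alone; median -0.84, adjusted p = 3.16e-22), with IFIT1 at -2.61 and IFIT3 at -2.39. Antigen presentation genes rose in 16 of 22 cases and fell in 5 (median 1.11, adjusted p = 3.79e-05), a call lost at an adjusted p = 0.16 with an estimated correlation. Within that list CD74 (2.09), HLA-DQB1 (2.68), the transactivator CIITA (1.74) and B2M (0.41) were higher, the peptide transporter TAP1 (-1.42) and the proteasome subunit PSMB9 (-1.23) were lower, and HLA-E was not called (0.03, adjusted p = 0.881). HLA genes share sequence, so the assignment of their reads is uncertain.

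The leukemia program and its signalling moved less evenly with shNAT10-1. The HOXA/MEIS1 list, which maintains MLL-rearranged leukemia, had 10 of 24 genes lower and 4 higher (12 and 4 adjusted over the list alone; median -0.40, camera adjusted p = 0.0105, and adjusted p = 0.138 with an estimated correlation). The receptor FLT3 (-1.52) and the chromatin reader PSIP1 (-1.60) fell, while MEN1 was not called (-0.07, adjusted p = 0.829). HOXA9 fell by 0.54 ± 0.16 (edgeR adjusted p = 0.00467), a call that ended without shNS replicate 2 (-0.35, adjusted p = 0.205) and without shNAT10-1 replicate 1 (-0.34, adjusted p = 0.134). MEIS1 fell by 0.61 ± 0.18 (adjusted p = 0.00488), and lost its call without shNS replicate 2 (-0.53, adjusted p = 0.0793) or shNAT10-1 replicate 2 (-0.47, adjusted p = 0.0818). Output genes of FLT3, STAT5 and MAPK signalling did not pass as a set (6 higher and 9 lower of 25; 7 and 9 adjusted over the list alone; median -0.15, adjusted p = 0.0638). They passed when scaled by library totals (median -0.27, adjusted p = 0.0494) and without shNS replicate 1 (median -0.21, adjusted p = 0.0171). The cytokine-induced CISH (-2.71), SOCS2 (-1.98) and CCND2 (-2.16) fell and PHLDA1 rose (1.89). Targets of p53 rose in 14 of 28 cases and fell in 4 (16 and 6 adjusted over the list alone; median 0.40, adjusted p = 0.0243, and adjusted p = 0.16 with an estimated correlation). BTG2 rose (1.51), CCNG1 (-1.79), FAS (-1.88) and GDF15 (-2.35) fell, and the cell-cycle inhibitor CDKN1A missed the threshold (0.28 ± 0.12, adjusted p = 0.0612). CDKN1A passed under DESeq2 (adjusted p = 0.0343) and limma-voom (adjusted p = 0.0385). BCL2 family members, which set the threshold for apoptosis, went both ways (5 higher and 2 lower of 15; 6 and 3 adjusted over the list alone; median 0.27, adjusted p = 0.18), with BMF (1.27) and BCL2L11 (0.90) higher. BCL2 fell by 0.53 ± 0.16 (adjusted p = 0.00655), and without shNS replicate 1 its value was -0.46 and the adjusted p = 0.101.

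Glycolysis and hypoxia genes rose with shNAT10-1 in 16 of 31 cases and fell in 6 (17 and 6 adjusted over the list alone; median 0.54, camera adjusted p = 0.00511, and adjusted p = 0.314 with an estimated correlation). Hexokinases HK1 (1.76) and HK2 (1.41) were higher and the glucose transporter SLC2A3 lower (-1.53). All 13 mitochondrially encoded genes rose (median 0.57, adjusted p = 2.34e-06, and adjusted p = 0.337 with an estimated correlation). Their share of all counts was 3.74% ± 0.19 (SD, n = 2) in shNS, 5.11% ± 0.32 (SD, n = 2) with shNAT10-1 and 6.74% ± 0.64 (SD, n = 2) with shNAT10-2. Nuclear oxidative phosphorylation genes did not pass (10 higher and 2 lower of 43; median 0.15, adjusted p = 0.297), but did without shNS replicate 2 (median 0.22, adjusted p = 0.0363) or shNAT10-1 replicate 1 (median 0.24, adjusted p = 0.043). Cholesterol and fatty acid synthesis split evenly (8 higher and 8 lower of 29; 8 and 9 adjusted over the list alone), with SCD (-2.07) and FADS2 (-2.09) lower and SQLE higher (1.08). Its median was 0.05 and its mean -0.31, the test pointed down (adjusted p = 0.317), and the median was -0.07 when scaled by library totals. Folding genes of the ER unfolded protein response (10 higher and 4 lower of 22; median 0.32, adjusted p = 0.276, and adjusted p = 0.0419 unfiltered) and of the cytosolic heat shock response (1 higher and 5 lower of 16; median -0.25, adjusted p = 0.276) did not pass as sets, though XBP1 fell (-1.85) and CRELD2 rose (1.46). Translation factors (2 higher and 8 lower of 35; 2 and 7 adjusted over the list alone; median -0.07, adjusted p = 0.121) passed only when scaled by library totals (median -0.19, adjusted p = 0.0395), unfiltered (median -0.08, adjusted p = 0.029) or without shNS replicate 1 (median -0.07, adjusted p = 0.0394). RNA modification genes had 2 higher and 8 lower of 35 (2 and 7 adjusted over the list alone; median -0.11, adjusted p = 0.219, and adjusted p = 0.0428 unfiltered), with IGF2BP1 at -0.72 and WTAP at 0.69. Replication-dependent histones, whose messages mostly lack a poly(A) tail, had 4 higher and 0 lower of 13 (3 and 0 adjusted over the list alone; median 0.49, adjusted p = 0.395). Stem and progenitor genes (3 higher and 1 lower of 9; 3 and 2 adjusted over the list alone; median 0.19, adjusted p = 0.701) did not pass. Nor did the lists that served as checks for other lineages, namely erythroid and megakaryocyte markers (2 higher and 2 lower of 7; median -0.37, mean 0.02, adjusted p = 0.905), lymphocyte markers (1 higher and 2 lower of 7; median -0.36, adjusted p = 0.18) and epithelial, fibroblast and endothelial markers (3 higher and 2 lower of 8; median 0.45, adjusted p = 0.601).

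With shNAT10-2 the interferon response, the set of antiviral genes that cells switch on when they sense interferon, was almost silent. Antigen presentation and inflammatory genes were lower as well, and so were the ATF4, serine and tRNA-charging genes. Granule genes of promyelocytes and genes of cholesterol and fatty acid synthesis were higher, and cell-cycle genes did not move as a set. In total 4209 genes changed against shNS (27.1% of those tested), 1967 higher and 2242 lower, and 1440 of them by at least 2-fold. The number was 2751 without shNS replicate 1 and 2704 without shNAT10-2 replicate 1. Of the 32 lists 13 moved, 5 up and 8 down, and with an estimated correlation the interferon list alone passed (adjusted p = 0.0024).

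All 39 interferon-response genes fell with shNAT10-2 (median log2 fold change -5.47, also with IFI27 at the bound given next), and the preset-correlation p of camera was too small for the program to store. OAS3 (ENSG00000111331.14, chromosome 12, 112938352 to 112973249), a sensor of double-stranded RNA, went from 10908 and 11020 counts in shNS to 19 and 9 (-9.42 ± 0.21, edgeR adjusted p = 4.15e-37), against 4310 and 4486 with shNAT10-1. The log2 fold change was -9.22 ± 0.21 for IFIT1, -6.98 for IFIT2, -7.78 for OAS2 and -10.36 for IFI44L. With so few counts left with shNAT10-2, the ± values of OAS3 and IFIT1 are smaller than the counting error. IFI27 had 1610 and 1984 counts in shNS, 1384 and 1716 with shNAT10-1 and 0 in both shNAT10-2 libraries, which makes it at least 1050-fold lower than in shNS against a floor of 3 counts over the group. Such floors and the intervals of low-count ratios cover counting error only. Of 425 genes lower by at least 4-fold, 38 belonged to the interferon list, 9 to the antigen presentation list and 6 to the ATF4 list. With shNAT10-1 237 genes were lower by that much, of which 2 were in the interferon list. Among transcription factors of the pathway STAT2 (-2.59) and IRF7 (-4.34) fell, while IRF3 (0.12, adjusted p = 0.644) and IRF8 (-0.27, adjusted p = 0.0791), singled out afterwards, were not called. Its receptor and kinase transcripts, singled out after the list result was seen, were not called (IFNAR1 -0.11, adjusted p = 0.603; IFNAR2 0.18, adjusted p = 0.562; JAK1 -0.06, adjusted p = 0.77; TYK2 -0.13, adjusted p = 0.484). Transcripts of the 22 interferon genes themselves were near 0 in every library, with 9 and 6 counts in shNS, 3 and 1 with shNAT10-1, and 3 and 2 with shNAT10-2.

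Antigen presentation and inflammatory genes were lower with shNAT10-2 too. Of 22 antigen presentation genes 18 fell and 0 rose (median -1.38, camera adjusted p = 3.57e-19, and adjusted p = 0.0902 with an estimated correlation), with TAP1 at -3.40, HLA-E at -1.84, B2M at -1.57, HLA-DQB1 at -2.40 and CD74 at -1.04. HLA-DPA1, with 81 and 93 counts in shNS and 0 in both shNAT10-2 libraries, was at least 51-fold lower, and the list median was the same with it at that bound. NF-kB and cytokine genes fell in 14 of 23 cases and rose in 1 (15 and 1 adjusted over the list alone; median -0.63, adjusted p = 1.67e-09, and adjusted p = 0.0902 with an estimated correlation). The chemokines CXCL10 (-5.25) and CCL4 (-2.87) and the signalling adaptor TRAF1 (-2.46) fell, and CXCL8 rose (0.46). Replication-dependent histones fell in 8 of 13 cases and rose in none (median -1.43, adjusted p = 2.93e-04, and adjusted p = 0.119 with an estimated correlation), with H2AC6 at -2.20. Histone copies share sequence, so their read assignment is uncertain. Of 7 lymphocyte markers 4 fell and 0 rose (median -0.79, adjusted p = 0.00497, and adjusted p = 0.175 with an estimated correlation), among them the B-cell factor PAX5 (-2.70). Its median, the same with CD7 (0 counts in both shNAT10-2 libraries) at its bound, was -1.20 without shNS replicate 2, and -1.37 and -1.55 without shNAT10-2 replicates 1 and 2.

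Amino acid supply genes fell with shNAT10-2 as well, by less for PHGDH. Of 28 ATF4 genes 24 fell and 1 rose (25 and 1 adjusted over the list alone; median -1.29, camera adjusted p = 3.57e-19), with TRIB3 at -3.36 ± 0.16, CHAC1 at -2.78, STC2 at -2.89 and SLC7A5 at -1.67. Of 23 serine, glycine and one-carbon genes 10 fell and 2 rose (11 and 2 adjusted over the list alone; median -0.30, and -0.19 without shNAT10-2 replicate 2; adjusted p = 3.75e-05). PHGDH had 573 and 444 counts (-1.72 ± 0.14, edgeR adjusted p = 3.28e-14), and PSAT1 (-1.85), PSPH (-1.74), SHMT2 (-1.27) and ALDH1L2 (-1.92) fell too. SLC1A4 fell by 0.49 ± 0.14 (adjusted p = 0.00537), a call that ended without shNS replicate 2 (adjusted p = 0.0679) or shNAT10-2 replicate 2 (adjusted p = 0.108). Of 20 aminoacyl-tRNA synthetases 11 fell and 2 rose (median -0.46, adjusted p = 3.75e-05), with WARS1, itself an interferon target, at -2.89 and GARS1 at -1.22. Each of these 3 lists lost its call, at a camera adjusted p = 0.0902 with an estimated correlation. The estimate was 0.098 for the ATF4 list, but -0.0092 for the serine list and -0.025 for the synthetases, under the preset 0.01. A higher correlation among genes thus does not account for the lost calls of the serine and synthetase lists.

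Myeloid genes gave mixed results with shNAT10-2. Of 14 neutrophil granule and promyelocyte genes 9 rose and 3 fell (10 and 3 adjusted over the list alone; median 0.67, camera adjusted p = 6.04e-06, and adjusted p = 0.268 with an estimated correlation). The primary granule proteins PRTN3 (2.76), AZU1 (1.84) and CTSG (1.65) rose, and MMP9 fell (-2.18). The monocyte list went both ways (7 higher and 13 lower of 34; 7 and 15 adjusted over the list alone; median -0.19, adjusted p = 0.912), with S100A8 (3.84), S100A9 (3.40) and LYZ (1.46) higher and FCER1G (-4.06) and NCF1 (-1.47) lower. Stem and progenitor genes (1 higher and 2 lower of 9; 2 and 2 adjusted over the list alone; median 0.22, adjusted p = 0.69) and immediate early genes (6 higher and 6 lower of 22; 6 and 7 adjusted over the list alone; median -0.16, adjusted p = 0.599) did not pass, though NR4A3 fell (-5.32, from 147 and 138 counts to 0 and 6). Erythroid and megakaryocyte markers (1 higher and 0 lower of 7; median 0.02, mean -0.24, test direction up, adjusted p = 0.509; median -0.02 when scaled by library totals) and epithelial, fibroblast and endothelial markers (1 higher and 0 lower of 8; median 0.38, mean -0.18, adjusted p = 0.377) did not pass.

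Cell-cycle genes did not move as sets with shNAT10-2. The G2/M list had 6 of 37 higher and 2 lower (median 0.15, camera adjusted p = 0.194), the S-phase list 4 of 40 higher and 2 lower (3 and 1 adjusted over the list alone; median 0.06, adjusted p = 0.437), and ribosome biogenesis 2 of 63 higher and 7 lower (1 and 6 adjusted over the list alone; median -0.02, adjusted p = 0.778). TOP2A (0.15, adjusted p = 0.42) and CDK1 (-0.05, adjusted p = 0.85) were not called, and CCNB1 rose (0.77). Cytosolic ribosomal protein genes rose in 25 of 77 cases and fell in 1 (26 and 1 adjusted over the list alone; median 0.25, adjusted p = 7.69e-05, and adjusted p = 0.69 with an estimated correlation), with RPL8 at 0.64 and RPLP0 at 0.57; many have processed pseudogenes that can share reads. Their median was 0.15 without shNS replicate 1 and 0.38 without shNS replicate 2, and their share of all counts was 8.58% ± 0.77 (SD, n = 2) in shNS, 8.42% ± 0.97 (SD, n = 2) with shNAT10-1 and 10.2% ± 0.11 (SD, n = 2) with shNAT10-2. Cholesterol and fatty acid synthesis rose in 15 of 29 cases and fell in 1 (20 and 2 adjusted over the list alone; median 0.45, adjusted p = 5.99e-05, and adjusted p = 0.135 with an estimated correlation), including FASN (1.23) and DHCR7 (1.08). All 13 mitochondrially encoded genes rose (median 0.85, adjusted p = 2.87e-10, and adjusted p = 0.289 with an estimated correlation), with MT-CO3 at 1.11. Nuclear oxidative phosphorylation genes rose in 14 of 43 cases and fell in 2 (15 and 2 adjusted over the list alone; median 0.26, adjusted p = 0.016, and adjusted p = 0.69 with an estimated correlation). Without shNS replicate 1 their median was 0.19 and the adjusted p = 0.116. The mitochondrial transfer RNA gene MT-TA, at 5.34 ± 0.63 the largest rise that met the naming rule, rested on shNAT10-2 replicate 2 (4039 counts, against 79 in replicate 1) and without it was 0.41 (adjusted p = 0.447).

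Other groups went both ways with shNAT10-2. Among BCL2 family genes 3 rose and 7 fell of 15 (5 and 7 adjusted over the list alone; median -0.31, camera adjusted p = 0.194, and adjusted p = 0.0497 unfiltered), with BCL2 at -1.36 ± 0.17 (edgeR adjusted p = 3.36e-09) and PMAIP1 at -1.42 lower and BIK higher (1.20). Targets of p53 had 6 higher and 5 lower of 28 (6 and 6 adjusted over the list alone; median -0.09, adjusted p = 0.658), with GDF15 at -4.45, and CDKN1A was not called (-0.14, adjusted p = 0.424). In the HOXA/MEIS1 list 4 rose and 8 fell of 24 (median -0.25, adjusted p = 0.426). HOXA9 (-0.40 ± 0.15, adjusted p = 0.0464) lost its call under DESeq2 (adjusted p = 0.109) and without shNS replicate 2 (-0.20, adjusted p = 0.55) or either shNAT10-2 library, and MEIS1 (-0.30, adjusted p = 0.205) and MEN1 (0.06, adjusted p = 0.874) were not called. MYC fell by 0.90 ± 0.13 (adjusted p = 4.56e-07). FLT3, STAT5 and MAPK output had 2 higher and 9 lower of 25 (4 and 9 adjusted over the list alone; median 0.03, mean -0.28, test direction down, adjusted p = 0.265; median -0.02 when scaled by library totals), with PIM1 at -1.09. Genes of the ER unfolded protein response fell in 8 of 22 cases and rose in 3 (10 and 4 adjusted over the list alone; median -0.23, adjusted p = 0.0543), with HERPUD1 at -1.77. That list passed under limma-voom (adjusted p = 0.0226), when scaled by library totals (adjusted p = 0.0401), unfiltered (adjusted p = 0.0159), and without shNS replicate 1 (adjusted p = 0.0167), shNAT10-1 replicate 1 (adjusted p = 0.0376) or shNAT10-1 replicate 2 (adjusted p = 0.0335). Heat shock genes (5 higher and 2 lower of 16; 6 and 2 adjusted over the list alone; median 0.25, adjusted p = 0.235) did not pass, but did unfiltered (median 0.27, adjusted p = 0.0118). Glycolysis genes (11 higher and 4 lower of 31; 12 and 4 adjusted over the list alone; median 0.12, adjusted p = 0.176) and lysosomal genes (11 higher and 8 lower of 30; 13 and 8 adjusted over the list alone; median 0.28, adjusted p = 0.194) did not pass. Iron and oxidative stress genes (6 higher and 6 lower of 22; 7 and 9 adjusted over the list alone; median -0.01, adjusted p = 0.69) did not pass either. VEGFA fell (-1.73), and HMOX1 fell (-1.12) where it had risen with shNAT10-1. RNA modification genes (3 higher and 7 lower of 35; median -0.07, adjusted p = 0.426) and translation factors (5 higher and 4 lower of 35; median 0.11, adjusted p = 0.426) did not pass either, while the RNA editing enzyme ADAR, which interferon induces, fell (-2.53).

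**Figure D2:**
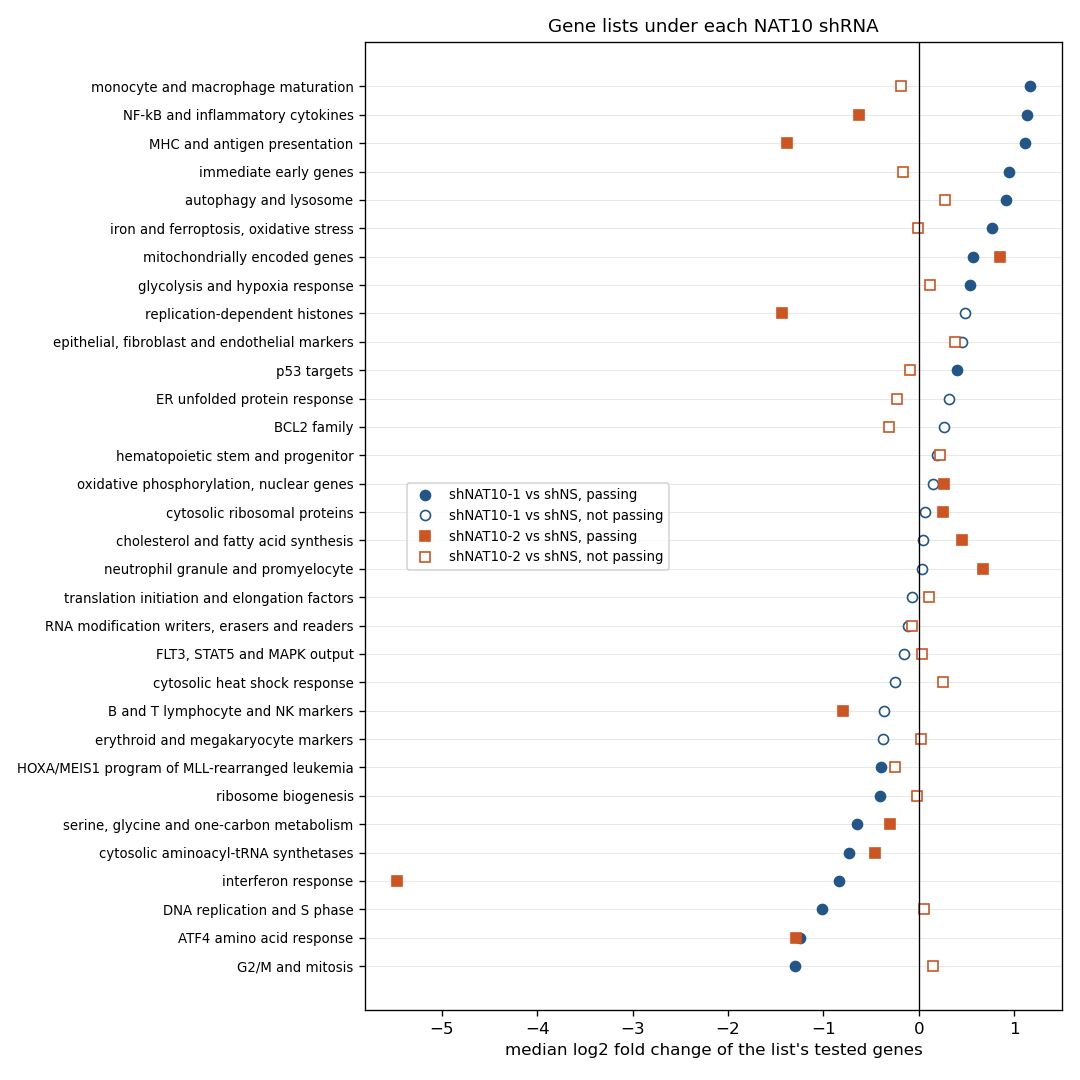
Median log2 fold change of each of the 32 gene lists against shNS, for shNAT10-1 (circles) and shNAT10-2 (squares); filled symbols passed camera with a preset correlation, and open ones did not. The ATF4 list lay at -1.24 and -1.29, the G2/M list at -1.30 and 0.15, and the interferon list at -0.84 and -5.47; 5 lists with medians near 0 changed sign when scaled by library totals.

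The next comparison asks which genes moved the same way with either hairpin. PHGDH, PSAT1, TRIB3, CXCL10 and MYC were lower with both, and S100A8, LYZ and HK3 were higher. In total 1823 genes changed the same way, 884 higher and 939 lower, and 539 were called in opposite directions, 359 of them higher with shNAT10-1 and lower with shNAT10-2. Independent lists of these sizes would share 357 higher and 405 lower genes, and 762 in opposite directions. Simulated unchanged groups that shared simulated controls had a mean of 0.05 such genes (0 to 1 over 20 draws). No gene was changed in those draws, so hardly any call was possible and the value is no baseline for the overlap. The controls are too few to split, so part of the excess over independent lists may come from the shared shNS libraries. The number was 1103 without shNS replicate 1, and scaling by library totals gave 659 higher and 1225 lower, so 35.0% in place of 48.5% were higher.

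Ranked by the smaller of the 2 changes, the gene highest under both hairpins was the transcription factor gene OLIG1 (ENSG00000184221.13, chromosome 21, 33070144 to 33072420), at 2.92 ± 0.14 with shNAT10-1 and 2.99 ± 0.14 with shNAT10-2 (edgeR adjusted p = 2.22e-22 and 1.28e-23). It went from 417 and 554 counts to 2542 and 3417, and to 3874 and 2919. The other 9 were MGAM2 (2.95 and 2.72), the protease inhibitor SLPI (2.79 and 2.21), ARRDC3 (3.07 and 2.14), the surface protease FAP (3.94 and 2.07), the hexokinase HK3 (2.02 and 2.95), the calcium-binding S100A8 (1.88 and 3.84), SCUBE1 (1.87 and 2.02), GAPT (2.12 and 1.73) and the lipid transporter ABCA5 (2.94 and 1.72). Among the 10 lowest, KLHDC7B fell by 6.87 with shNAT10-1, and its 901 counts in shNS against 1 with shNAT10-2 made a ratio of 792 (95% counting interval 142 to 31300). NEXN (-5.27 and -4.93), CXCL10 (-4.59 and -5.25), CXCL11 (-4.33 and -6.99), TRIB3 (-4.67 and -3.36), ADAMTS14 (-3.37 and -3.17), STC2 (-5.23 and -2.89), RGS16 (-3.05 and -2.81) and the potassium channel subunit KCNG1 (-4.24 and -2.66) followed. ADM2 had 465 counts in shNS against 3 with shNAT10-1, a ratio of 125 (42.6 to 609), and fell by 2.89 with shNAT10-2.

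Across the 15511 tested genes, which are not independent replicates, the log2 fold changes of both hairpins had a Pearson correlation of 0.291 and a Spearman correlation of 0.326. Simulated unchanged groups that shared simulated controls gave 0.48 and 0.446. The covariance was 0.251 against a simulated 0.0555, a difference of 0.196, and 62.8% of genes had the same sign against a simulated 66.3%. No gene was changed in those draws, so their correlations and share of same signs came from the shared controls alone. The lower observed correlations and share therefore do not show that the hairpins agreed less than unrelated changes would. Without shNS replicate 1 the Pearson correlation was 0.454.

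**Figure D3:**
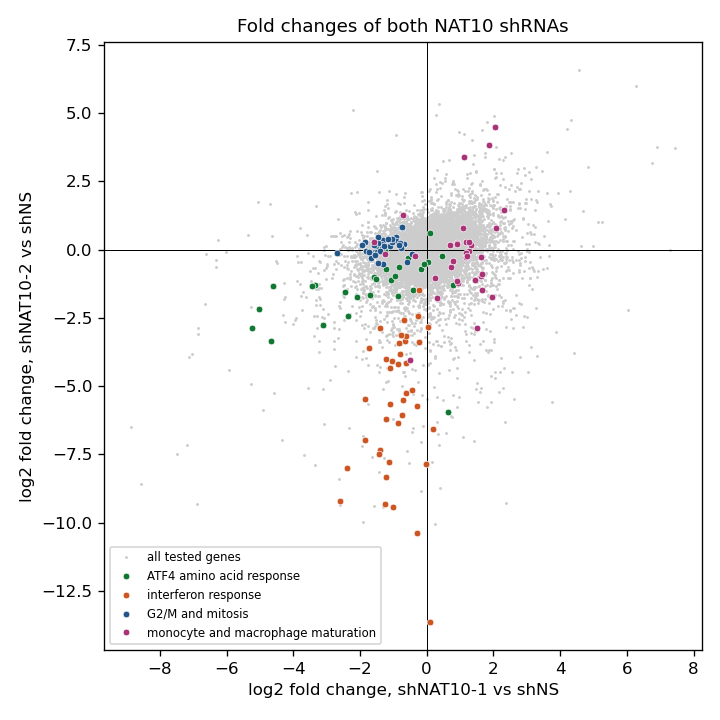
Log2 fold change of each tested gene with shNAT10-1 (horizontal axis) and shNAT10-2 (vertical axis) against shNS, with members of 4 lists coloured; the lowest fitted values belong to genes near 0 counts and depend on the prior count. ATF4 genes lie lower left (medians -1.24 and -1.29), G2/M genes to the left of 0 alone (-1.30 and 0.15) and interferon genes far down (-0.84 and -5.47).

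Transcript levels were also compared directly between the hairpins, as shNAT10-2 minus shNAT10-1. Cell-cycle genes were higher with shNAT10-2, and the interferon, antigen presentation, inflammatory, monocyte and lysosomal genes were lower. In total 5690 genes differed, 2733 higher and 2957 lower, 2523 of them by at least 2-fold, and 20 of the 32 lists passed, 9 up and 11 down. Scaling by library totals gave 3263 genes higher and 2589 lower, so 55.8% in place of 48.0% were higher. With an estimated correlation 5 lists passed, the interferon list at an adjusted p of 0.0046 and the others at 0.0455. These were the G2/M list (35 of 37 higher, 0 lower; median 1.43, camera adjusted p = 4.40e-24), the S-phase list (34 of 40 higher, 0 lower; median 1.03, adjusted p = 1.26e-16), the interferon list (39 of 39 lower; median -4.65, adjusted p = 3.74e-202), antigen presentation (20 of 22 lower, 0 higher; median -1.98, adjusted p = 2.59e-27) and NF-kB genes (23 of 23 lower; median -1.53, adjusted p = 1.94e-27). As sets, the ATF4 list (median 0.29, camera adjusted p = 0.134) and the aminoacyl-tRNA synthetases (median 0.34, adjusted p = 0.0654) were not called between the hairpins. Single members did differ. Of 28 ATF4 genes 12 were higher and 8 lower with shNAT10-2, and of 20 synthetases 9 were higher and 2 lower (11 and 2 adjusted over the list alone). Among genes higher with shNAT10-2 were the splicing factor ESRP1 (3.98 ± 0.29), the tubulin regulator STMN1 (3.32 ± 0.18) and GINS1 (3.20 ± 0.30). ADM2 had 55 counts with shNAT10-2 against 3 with shNAT10-1, and MT-TA was higher through 1 library (4.97, and 0.05 without shNAT10-2 replicate 2). Lower with shNAT10-2 were IFI44L (-10.08 ± 0.27) and OAS3 (-8.41 ± 0.20). IFI27 was at least 1130-fold lower, HLA-DPA1 at least 266-fold and the coiled-coil gene TMCC3 at least 101-fold, each with 0 counts in both shNAT10-2 libraries. HMOX1 (-3.28) and CD74 (-3.13), higher with shNAT10-1 and lower with shNAT10-2, also differed, and PRTN3 (2.18) was higher with shNAT10-2.

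The authors' deposited tables and the edgeR fit were compared gene by gene. The authors' deposited tables called 4025 genes with shNAT10-1 (1964 higher, 2061 lower) and 3065 with shNAT10-2 (1438 higher, 1627 lower) at the same threshold. Across 15507 shared genes the log2 fold changes of the authors' deposited tables correlated with the edgeR values at 0.9995 and 0.999. All 4001 and 3016 genes called in both had the same sign. Among these shared genes, 19 and 49 were called in the authors' deposited tables alone, and 1613 and 1193 in the edgeR fit over 3 groups alone.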

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

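Of the tests in this part, those of knockdown strength, of mitochondrial content, and of GC content and length in the serine and synthetase lists were chosen after the result was seen, and that of the receptor and kinase transcripts after the interferon list result but before their own values. The ATF4 targets and the aminoacyl-tRNA synthetases were lower with both hairpins and not called as sets between them. The other results given here stood out because the effects of the hairpins differed when tested directly. That test was shNAT10-2 minus shNAT10-1, with edgeR for genes and camera for lists. By that test 5690 genes differed, and 20 of 32 lists passed; differences are log2 values of shNAT10-2 minus shNAT10-1.

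Interferon-response genes (median difference -4.65), antigen presentation (-1.98) and NF-kB genes (-1.53) were far lower with shNAT10-2, which left NAT10 no lower than shNAT10-1 did. Against shNS, loss of a receptor or kinase transcript was argued against, since the lowest of IFNAR1, IFNAR2, JAK1 and TYK2 was TYK2 at -0.13. Removing a trend on GC content and gene length left the interferon median against shNS at -5.23. Between the hairpins IFNAR1 (-1.39), TYK2 (-1.09) and IFNAR2 (-0.70) were lower with shNAT10-2, and JAK1 was not called (-0.18). Those lower transcripts had risen with shNAT10-1 against shNS (IFNAR1 1.27, TYK2 0.96, IFNAR2 0.88), where the interferon genes fell. A subline with gained or lost chromosomes cannot be told apart from an effect of the hairpin, because the chromosome median farthest from 0, that of chromosome 21, was -0.12 (SE 0.05), which is short of the 0.3 set for a gain or loss but not clearly inside the 0.15 set against one, and a subline without such changes would leave no mark. An off-target effect of shNAT10-2, a loss of a pathway protein without loss of its transcript, and an effect of NAT10 itself stay open and were not tested. With shNAT10-1 the interferon genes were also lower than in shNS, so a raised interferon state of the shNS libraries, which both contrasts share, stays open for that smaller part.

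Cell-cycle genes (median differences 1.43 for G2/M and 1.03 for S phase) were lower, and monocyte (-1.30), lysosomal (-0.54), iron and oxidative stress (-0.78) and immediate early genes (-0.96) higher, with shNAT10-1 than with shNAT10-2. The monocyte, lysosomal, iron and immediate early lists lost their call, at an adjusted p = 0.0811, 0.0952, 0.0666 and 0.113 with an estimated correlation. After a trend on GC content and length was removed, the medians against shNS with shNAT10-1 were -1.22 for G2/M and 1.08 for the monocyte list, which argues against that bias as the whole cause. A higher mitochondrial content as the cause of the G2/M fall was argued against too. All 13 mitochondrially encoded genes rose with shNAT10-2 as well, while the G2/M median with shNAT10-2 was 0.15. Their median was 0.85 against 0.57 with shNAT10-1, a difference not called (camera adjusted p = 0.244). Against shNS the list had an adjusted p = 0.289 (shNAT10-2) and 0.337 (shNAT10-1) with an estimated correlation. RNA quality was not measured in any other way, so a difference in it stays open. A stronger NAT10 knockdown with shNAT10-1 cannot be told apart from an effect peculiar to that hairpin, because the difference in NAT10 was 0.39 (SE 0.17; not called, adjusted p = 0.0623) and only 2 knockdown levels were measured, and no biological explanation beyond the hairpin was tested.

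ATF4 targets, serine synthesis genes and aminoacyl-tRNA synthetases were lower with both hairpins, though with shNAT10-2 each list lost its call (adjusted p = 0.0902 with an estimated correlation), and the size differed for the serine list (0.11; adjusted p = 0.111 with an estimated correlation), PHGDH (2.53) and PSAT1 (1.46). For the ATF4 targets, independent scatter of single genes in the shared shNS libraries was argued against. The lowest ATF4 median among 20 simulated draws was -0.09, against observed values of -1.24 and -1.29. Each gene was drawn on its own, so the draws cannot decide on a chance shift that these genes share in the shNS libraries. The higher of the ATF4 medians after correction for GC content and length was -1.18, which argues against that bias for the ATF4 targets, as does the synthetase median with shNAT10-1 (-0.73 before and -0.82 after, SE 0.19) for that list. It cannot be told apart from an effect of the hairpins for the synthetases with shNAT10-2 (-0.46 before and -0.32 after, SE 0.18) or for the serine list (-0.65 and -0.60, SE 0.39, with shNAT10-1; -0.30 and -0.10, SE 0.31, with shNAT10-2), because these medians lie within 2 standard errors of 0. An effect of NAT10 loss on the ATF4 targets stays a hypothesis, and a raised amino acid stress response in both shNS libraries would give the same values and was not tested.

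The other differing lists are given by their median difference. Higher with shNAT10-2 were neutrophil granule genes (1.49), heat shock genes (0.43), cholesterol and fatty acid synthesis (0.37), ribosome biogenesis (0.34), translation factors (0.26) and ribosomal proteins (0.14). Lower with shNAT10-2 were replication-dependent histones (-1.84), p53 targets (-0.59), the ER unfolded protein response (-0.52) and the BCL2 family (-0.41). With an estimated correlation each of these 10 lists lost its call, as did the serine, monocyte, lysosomal, iron and immediate early lists. Among single genes BCL2 (-0.83), CDKN1A (-0.42) and SLC1A4 (-0.36) were lower with shNAT10-2 than with shNAT10-1.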

How the results depend on the processing

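The fits without the interferon and antigen presentation lists, and DESeq2 over the 4 libraries of the groups compared (4057 and 3063 calls), were chosen after seeing the data, and the other alternatives before. RLE factors and a filter of 1 CPM in 2 libraries left all 315 tests of named genes and all 64 list tests against shNS with the same direction and on the same side of the threshold. Scaling by library totals ended 3 gene calls and added 3 list calls. Leaving the low counts in ended 4 gene calls and added 1, and added 6 list calls. DESeq2 ended 7 gene calls and added 1, and gave 4772, 3446 and 4948 genes for shNAT10-1, shNAT10-2 and their difference, and 1439 changed the same way; limma-voom gave 5664, 4361, 5674 and 1886. NAT10 kept its call in every fit run, and the value nearest 0 with 1 library left out was -1.78 with shNAT10-1 and -1.35 with shNAT10-2.

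A minimum log2 fold change of 1, a stricter criterion by construction, gave 2232, 1440 and 2523 genes, and 427 changed the same way. With an estimated correlation 10 lists passed with shNAT10-1 and 1 with shNAT10-2, in place of 17 and 13; fry gave 24 and 17. Without a filter the correlation of the fold changes was 0.432 in place of 0.291, and the cause was not tested. Without the interferon and antigen presentation lists it was 0.299, with 1788 genes changed the same way. Fitting the groups compared alone turned the test direction of the erythroid list with shNAT10-1 (median -0.39) and of the monocyte list with shNAT10-2 (median -0.19), both far from the threshold.

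Leaving out 1 library leaves an arm with a lone sample, which is assumed to vary like the other groups, and lets 16434 to 16546 genes past the filter in place of 15511. Calls ran from 4166 to 5547 with shNAT10-1, from 2704 to 4660 with shNAT10-2 and from 4404 to 5537 for their difference. Genes changed the same way ran from 1103 (without shNS replicate 1) to 1809, and the correlation from 0.244 (without shNAT10-2 replicate 1) to 0.454 (without shNS replicate 1); beyond the fewer samples, the cause was not tested. Signs turned, with no turned value past the threshold, for MEN1 with shNAT10-1 (-0.19 to 0.03) and shNAT10-2 (-0.03 to 0.14), PDGFRB with shNAT10-2 (-3.68 to 0.19), and in test direction for ribosomal proteins (-0.04 to 0.18), neutrophil genes (-0.11 to 0.13) and stem genes (0.02 to 0.45) with shNAT10-1 and the monocyte list with shNAT10-2 (-0.19 to -0.13). Without shNS replicate 1, 20 gene calls ended, the highest number, and without shNAT10-1 replicate 1, 6, the lowest.

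The replicate numbers gave no clear pairing of the samples. Deviations from the group means of libraries with the same number correlated at 0.13 between shNS and shNAT10-1, which leaves a weak pairing there possible. The value was -0.019 between shNS and shNAT10-2, and -0.039 between the hairpins. With the replicate block 5722, 4397 and 5833 genes were called and 1905 changed the same way, and 17 and 14 lists passed; CDKN1A with shNAT10-1 (adjusted p = 0.0216) and the ER unfolded protein list with shNAT10-2 (adjusted p = 0.0419) were among the calls it added. At this depth and with 2 libraries per group, changes of 1.5-fold were recovered in 40.3% (shNAT10-1) and 26.9% (shNAT10-2) of simulated cases, so a gene not called is not shown to be unchanged.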

Other observations

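Both observations here were chosen after the data were seen, and no explanation was tested. Metallothionein genes, which bind zinc and copper, rose with shNAT10-2 in 5 of 6 tested cases (median log2 fold change 1.80) and with shNAT10-1 in 4 of 6 (median 0.86). With shNAT10-2 MT1F rose by 2.44 ± 0.21 (edgeR adjusted p = 2.29e-13), MT1G by 2.04 ± 0.27 and MT2A by 1.01 ± 0.15, and MT1X (2.85) lost its call without shNAT10-2 replicate 1 (adjusted p = 0.0575). With shNAT10-1 MT1F rose by 1.35 ± 0.22 (adjusted p = 2.68e-06), while MT2A (0.40), MT1E (0.79) and MT1G (0.94) each lost their call when 1 library was left out, with the highest adjusted p-values at 0.741 (without shNAT10-1 replicate 2), 0.123 (without shNS replicate 1) and 0.262 (without shNAT10-1 replicate 1). The direction of the called genes was the same with RLE factors and library totals. These genes are near-identical copies, so the assignment of reads among them is uncertain.

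A few genes went between at least 100 counts in each library of 1 group and at most 3 counts in another group as a whole. Against shNS these were ADM2 with shNAT10-1, and IFI27, KLHDC7B, TMCC3, OTOF and the unnamed ENSG00000225886 with shNAT10-2, of which IFI27 alone is in the interferon list. TMCC3 had 140 and 152 counts in shNS, 146 and 133 with shNAT10-1 and 0 in both shNAT10-2 libraries, and OTOF had 132 and 148, 33 and 26, and 0 in both. ANXA8 went the other way, with 2 and 1 counts in shNS, 30 and 33 with shNAT10-1 and 150 and 124 with shNAT10-2.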
